A study of Mus musculus with 28 samples.

How the data were processed

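Total RNA of mouse liver was labelled by reverse transcription with amino-allyl nucleotides, coupled to Cy3 or Cy5 and hybridised together with saline reference RNA, per the labels' protocols. Luciferase RNA and a commercial mix of calibration RNAs were added before labelling, per the same protocols. The deposited file of each array holds the median intensity of each spot in the treated and the reference channel, with the median and SD of the local background, per the file headers. These intensities were not background-subtracted or normalized. The image software and its settings are not given in the sources used here, and the files carry no spot flags and no scan date. The authors also deposited a series table with a log2 ratio per probe and array. Set against the scanner values, its columns ran in the direction of treated over reference on a log2 scale, with r of 0.677 to 0.965 across genes (median 0.886) and no centring of genes. How the authors normalized and centred it is not given in the sources used here, and its column medians ran from 0.157 to 0.88 for adefovir in Cy3, -0.983 to 0.00 for adefovir in Cy5, 0.21 to 0.73 for tenofovir in Cy3, -1.45 to 0.30 for tenofovir in Cy5, -0.16 to 0.24 for single positive-control animals, 0.42 to 0.63 for the pool in Cy3 and -0.14 to -0.10 for the pool in Cy5.

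Each array carried 578 spots, of which 360 belonged to 120 gene probes with 3 spots each, beside 31 control probes. The platform's annotation paired 110 probes with a gene. The other 10 are named only in the scanner files: they are counted in all tests and lists and are not named in the text. The symbols of 115 probes matched a current symbol, those of 3 a synonym and those of 2 no single gene in the RefSeq table of assembly GRCm38.p6. The files name no genome build, so no coordinates are printed. Gapdh has 3 probes, and the brightest one is named. Probes of close paralogs, among them Cyp2b10 and Cyp2b13, Cyp1a1 and Cyp1a2, Cyp2a4, Cyp3a41a and Cyp2c40, can cross-hybridise, and their values are uncertain in that respect.

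Groups were taken from the sample titles. Treated and reference channels follow the dye labels, and every ratio was turned to treated over reference. A spot was called above background when its median exceeded the local background median by 2 background SDs, and a probe when most of its spots were. Probes above background in the treated channel numbered 64 to 80 with adefovir in Cy3 and 38 to 60 in Cy5, 64 to 88 and 30 to 47 with tenofovir, 63 to 84 for single positive-control animals, and 53 to 55 and 30 to 43 for the pool. The lowest correlation between arrays of the same dye orientation was -0.27. No pair of arrays was identical. At most 6 gene spots per channel were saturated, and they were kept. The number of arrays limits the precision.

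Analyses used R 4.3.3 with limma 3.58.1, and figures Python 3.11.15 with matplotlib 3.10.9. Background was corrected with normexp at an offset of 50, and each array was normalized by loess with a span of 0.3 over gene spots, control spots having weight 0. Spots of a probe were averaged. The 2 arrays of an antiviral animal were averaged to 1 value, so a dye effect cancels. Across genes these 2 arrays correlated at a median r of 0.274 (-0.112 to 0.682), or 0.613 (0.341 to 0.823) with the dye effect removed. The dye effect of each probe, estimated from the antiviral dye exchanges (SD 0.137 over probes), was subtracted from the positive-control arrays, which have 1 orientation only. It correlated across probes at r = 0.510 with the dye effect measured on the pool arrays. A linear model with 1 mean per group was fitted over the 14 animals (11 residual degrees of freedom, prior 3.36), with eBayes and Benjamini-Hochberg adjustment at 0.05 over 120 probes. The positive-control pool arrays entered no test. Tests against the saline pool are tests of the mean ratio against 0. They measure the spread between treated animals only, and the sample labels give 10 saline animals in the pool where the treatment protocol gives 5. The position of an array on its slide coincides with dye orientation, and each slide holds 1 animal.

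A channel below background on all arrays of a group gives only a bound. The bound is the mean normalized level of the bright channel over that of the higher of the dim probe and the dimmest probe above background, after loess and Aquantile scaling, and it is open to dye bias in the positive control. No fold is given where the bound is under 1 or both channels are below background.

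Before the data were examined, 18 gene lists were fixed, of which 9 had at least 3 measured members and were tested with fry. The aryl hydrocarbon receptor list had 2 measured members, Cyp1a1 and Cyp1a2, and the clock gene list 1, Nr1d2. The other small lists, markers of non-hepatocyte liver cells included, had too few members on the array. Named genes followed a rule fixed at the same time. It takes up to 20 called genes with the largest change and 1 sign in all animals, a fixed set of P450 and receptor genes whether called or not, and up to 4 members per list with the smallest p. Genes named beyond it, such as Acss2 in comparisons where it did not pass, were chosen after their values were seen.

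The pipeline was tested on 20 simulated data sets of 120 probes. Against the saline pool, 60.6% of true log2 changes of 0.5 were recovered for adefovir and 71.2% for tenofovir, and 100.0% of changes of 1 for each, with 1.88% and 1.36% of calls on unchanged genes. For the positive control 47.5%, 86.2% and 99.4% of changes of 0.5, 1 and 2 were recovered, and 25.6% of calls fell on unchanged genes, or 7.48% with that group fitted alone. Estimates were compressed, a true change of 1 giving 0.786 for adefovir and 0.628 for the positive control. The simulations gave the saline pool no deviation of its own. They also gave every group the same dye effect per probe, and equal numbers of rises and falls. Their shares of calls on unchanged genes therefore leave out false calls from the pool in the tests against saline. For the positive control they also leave out false calls from a dye effect of its own or from the scaling.

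Alternatives were no background correction, a normexp offset of 10, centring on the array median, on calibration spots or on luciferase spots, a filter on dim probes, medians of spots, robust eBayes, array weights, a fit of all arrays with the animal as a random block, fits of the compared groups alone, a replicate block, single dye orientations, other dye corrections, the series table, and leaving out each animal. Centring on Actb, Gapdh and Ppia, a filter on the positive control's saline signal and a simulated pool of 5 animals were chosen after seeing the data.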

Results

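The labels of the series ask how antivirals of the acyclic nucleoside phosphonate type bear on the expression of cytochrome P450 genes, the family of heme enzymes that oxidises drugs, steroids and fatty acids. Liver RNA of 14 treated female C57BL/6 mice was hybridised on 2-colour arrays of a focused design with 120 gene probes for 118 genes of drug, sterol and bile acid metabolism. Adefovir dipivoxil and tenofovir disoproxil were given to 5 animals each, at 25 mg/kg by intraperitoneal injection on 3 days. The positive control, 4 animals, received phenobarbital at 60 mg/kg, a classic inducer of drug metabolism, plus a single dose of 80 mg/kg β-naphthoflavone, a ligand of the aryl hydrocarbon receptor, on day 2. Livers were taken on day 4, 24 hours after the last treatment. Each antiviral animal had a pair of arrays with the dyes exchanged, whereas each positive-control animal had 1 array, always with the treated RNA in Cy3. A further 4 arrays, 2 in each dye orientation, carried pooled positive-control RNA. The other channel of all 28 arrays held pooled liver RNA of saline-treated mice, which acts as a single control sample, so tests against it leave out the spread among saline animals. On most arrays, 67 of the 120 probes stood above background in at least 1 channel. In the saline channel, 38 to 78 probes did so per antiviral array but 9 to 29 on the single-animal arrays of the positive control, whose file headers mark the Cy5 channel as bad.

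After adefovir dipivoxil, RNA levels fell for Cyp26a1, which codes for a retinoic acid hydroxylase, and for Cyp1a2, a drug-oxidising enzyme induced through the aryl hydrocarbon receptor. Cyp26a1 fell by 1.07 on the log2 scale (SE 0.116, SD 0.288 between animals, n = 5, adjusted p = 2.46e-05) and was lower in 5 of 5 animals. Its signal in the treated channel stood above background on 1 of 10 arrays, against 9 of 10 in the saline channel, so the size of the fall depends on the background level and no fold is given (-1.57 to -0.75 over 14 alternatives). Cyp1a2 fell by 0.59 (SE 0.127, SD 0.297, n = 5, adjusted p = 0.0203), or 1.51-fold, again in 5 of 5 animals. No gene rose among the 120 probes tested with limma, and 15 probes had an unadjusted p under 0.05. Some alternatives did call genes higher, 10 on arrays with treated RNA in Cy5 alone, 2 with array weights, 1 with the animal as a random block and 1 without positive-control animal 2.

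The other genes did not pass after adefovir. The 95% intervals lay within 0.5 log2 units of 0 for 112 of 120 probes. Of all probes, 67 stood above background on most arrays and 24 on none. A narrow interval of a dim probe does not show unchanged RNA. By list, 21 of 32 P450, 3 of 7 bile acid synthesis and 1 of 6 steroidogenesis genes stood above background on most arrays. Cyp2b10, the main phenobarbital-inducible P450, had a log2 ratio of -0.05 (95% interval -0.22 to 0.13), and the ethanol-inducible Cyp2e1 had 0.12 (-0.09 to 0.32). Cyp1a1 was not above background in either channel on any adefovir array. Among the 32 measured P450 genes, 2 fell and 30 did not pass, and the same 2 passed when adjusted over the list alone. The list had a median of -0.04, with fry's adjusted p of 0.0762 for a shared direction and 1.53e-06 for change in either direction. It holds the called Cyp26a1 and Cyp1a2, and fry was not run without them, so a wider P450 change is not shown. The other tested lists hold neither gene and did not pass for change in either direction (smallest adjusted p by fry 0.159). Steroid hydroxylase Cyp17a1 had a log2 ratio of -0.34 (adjusted p = 0.39), Cyp2a4 0.26, Cyp2a12 0.17 and Cyp2d22 0.01, none of them past the threshold. All 9 measured targets of the nuclear receptors CAR and PXR failed to pass, among them Cyp2b13 at -0.03, the transporter Abcc3 at 0.08 and Alas1, the first enzyme of heme synthesis, at 0.14. None of the 18 cholesterol synthesis genes passed, with Fdps at -0.30 (SD 0.586), Cyp51, lanosterol 14-demethylase, at -0.14, Mvd at -0.10 and Dhcr7 at -0.09. Acss2, which makes acetyl-CoA from acetate in the cytosol, had -0.38 with an SD of 0.536 between the 5 animals. Of 7 bile acid synthesis genes none passed either (fry's adjusted p = 0.0509, median -0.08), including Cyp7a1, the rate-limiting enzyme, at -0.05, Cyp8b1 at 0.02, Cyp27a1 at -0.00 and the sterol carrier Scp2 at -0.09. The 12 transporters held no call, with the bile salt export pump Abcb11 at -0.23, the bile acid importer Slc10a1 at -0.13, Abcb1a at -0.21 and Abcg8 at 0.15. Scap, which escorts sterol-responsive transcription factors, had 0.24 (adjusted p = 0.169) and was the 1 gene of 8 in the sterol regulation list that passed when adjusted over the list alone. Of 24 nuclear receptor and coregulator genes none passed (fry's adjusted p = 0.0978), with Nr1i3, the receptor CAR itself, at 0.15, Ppara at 0.20 and Nr5a2 at -0.13. The 6 steroidogenesis genes and the 4 probes of reference genes held no call (fry's adjusted p = 0.189 and 0.616), with Actb at -0.02 and the brightest Gapdh probe at -0.05. The Cyp1a2 call was lost when arrays were centred on their median, on calibration spots or on luciferase spots, when adefovir animals were fitted alone, in the deposited series table, and without adefovir animal 2, 3 or 4, with adjusted p between 0.000204 and 0.749 over 15 alternatives.

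After tenofovir disoproxil, Cyp26a1 fell as well, and Acss2 with it. Cyp26a1 fell by 1.07 (SE 0.116, SD 0.271, n = 5, adjusted p = 2.63e-05), in 5 of 5 animals. With the treated channel above background on 2 of 10 arrays, no fold is given here either (-1.42 to -0.71 over 14 alternatives). Acss2 fell by 0.74 (SE 0.163, SD 0.245, n = 5, adjusted p = 0.0269), or 1.67-fold, in 5 of 5 animals. Against the same saline pool Acss2 also averaged -0.38 after adefovir, not called, and -0.51 in the positive control, where it was called. A saline pool that happened to be high in Acss2 could lower every group and stays open. As after adefovir, no gene rose by limma's test, and 20 probes had an unadjusted p under 0.05. Alternatives called 27 genes higher with luciferase centring, 17 and 11 on arrays with treated RNA in Cy3 or Cy5 alone, 3 with array weights, 2 with the animal as a random block, 1 with tenofovir animals fitted alone and 1 without positive-control animal 4. The random-block fit, tenofovir animals fitted alone and arrays with treated RNA in Cy3 alone also called more genes lower than the main fit.

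Below the threshold after tenofovir, several sterol genes had negative ratios in each of the 5 animals. Of 18 cholesterol synthesis genes none passed over all probes, but Cyp51 (-0.50, adjusted p = 0.112) and Mvd (-0.34, adjusted p = 0.0982) passed when adjusted over the list alone. Farnesyl diphosphate synthase Fdps had -0.49 (SD 0.0891), Lss, which closes the sterol ring, -0.33, and Fdft1 -0.30. The list had a median of -0.15 and an adjusted p of 0.0762 by fry, and its median turned to 0.06 with centring on calibration spots. Of 32 P450 genes 1 fell and 31 did not pass, while 3 passed when adjusted over the list alone, namely Cyp26a1, Cyp17a1 (-0.58, adjusted p = 0.0703) and Cyp51. Fry gave an adjusted p of 0.170 for a shared direction of the P450 list and 3.40e-06 for change either way. The latter includes the called Cyp26a1 and was not repeated without it. No other tested list passed for change either way (smallest adjusted p by fry 0.0845, cholesterol synthesis). Cyp1a2 had -0.22 (95% interval -0.49 to 0.05), Cyp2a4 0.37 (adjusted p = 0.159), Cyp2a12 0.18, Cyp2d22 0.13, Cyp3a41a -0.16 and Cyp2e1 0.01. Cyp2b10 had -0.01 (-0.19 to 0.17), and Cyp1a1 again stayed below background in both channels. The 9 CAR and PXR targets held no call (fry's adjusted p = 0.516), with Abcc3 at 0.07 and Alas1 at -0.06. In the bile acid list 0 of 7 passed in limma's test (fry's adjusted p = 0.0762), with Cyp8b1, the sterol 12α-hydroxylase, at -0.48 but negative in 3 of 5 animals, Cyp7a1 at 0.01 and Cyp27a1 at -0.06. Of 12 transporters none passed, Slc10a1 having -0.16, Abcg8 0.23, Abcg5 0.11 and Abcc2 0.15. The 24 nuclear receptor genes moved upward as a set by a median of 0.06 (fry's adjusted p = 0.0344), though none passed singly and 8 were above background. Measured members included Ppara at 0.27, Hnf4a at 0.18 and Nr1i3 at 0.12. That set call was lost with centring on the array median, on calibration spots or on Actb, Gapdh and Ppia (adjusted p = 0.142, 0.0926 and 0.150), with the filter on dim probes, with medians of replicate spots, on arrays with treated RNA in Cy5 alone, and without tenofovir animal 1, 3, 4 or 5. Its adjusted p ranged from 0.00422 to 0.213 over 13 alternatives and up to 0.0894 with an animal left out. Scap had 0.10 and Scarb1, a lipoprotein receptor, 0.10 in a sterol regulation list without calls (fry's adjusted p = 0.0762). In the steroidogenesis list (fry's adjusted p = 0.221) Cyp17a1 passed when adjusted over the list alone, and the reference genes held no call (0.0537), with Actb at 0.15. The Acss2 call was lost with calibration-spot centring, on arrays with treated RNA in Cy5 alone, and without tenofovir animal 1, 2, 3 or 4, with adjusted p from 0.000214 to 0.0916 over 15 alternatives and up to 0.126 with an animal left out.

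**Figure D1:**
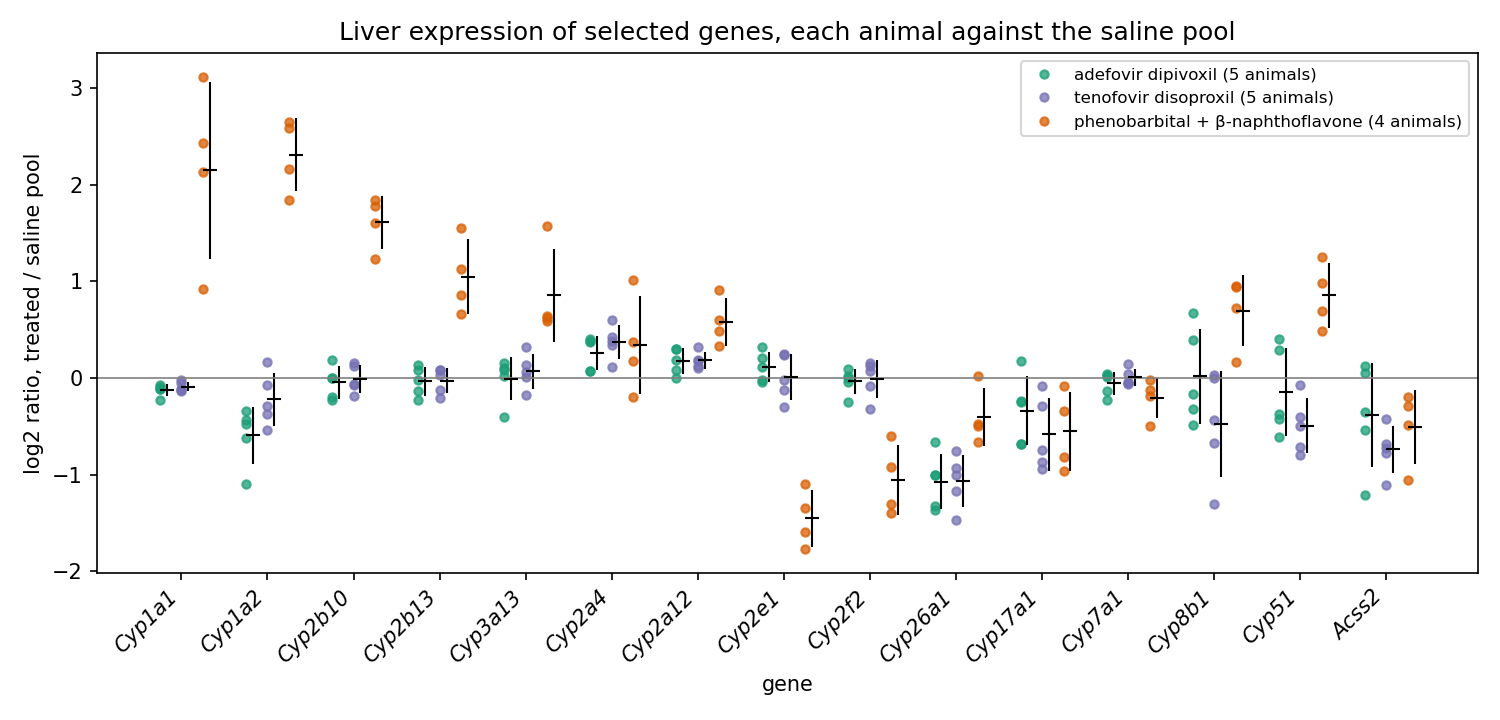
Log2 ratio of treated over saline-pool RNA (vertical axis) for selected genes (horizontal axis). Each point is an animal (5 adefovir, 5 tenofovir, 4 positive control). Each dash is a group mean, and its vertical bar reaches 1 SD between animals to either side. All antiviral animals lie below 0 for Cyp26a1, with means of -1.07 in both groups, and the 4 positive-control animals average 2.31 for Cyp1a2 and -1.45 for Cyp2e1.

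**Figure D2:**
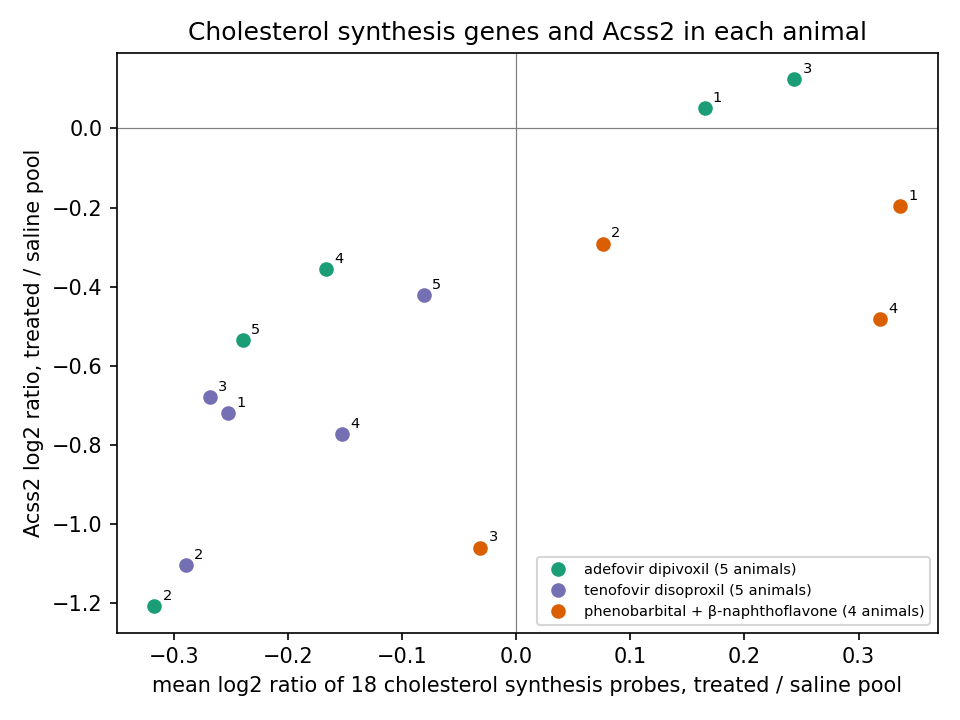
Mean log2 ratio of the 18 cholesterol synthesis probes (horizontal axis) against the log2 ratio of Acss2 (vertical axis), treated over saline pool, with a point per animal, numbered and coloured by group. Tenofovir animals lie at list means of -0.29 to -0.08, while adefovir animals spread from -0.32 to 0.24 and their Acss2 ratios from -1.21 to 0.12.

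Adefovir and tenofovir are both acyclic phosphonates of adenine, and tenofovir carries an additional methyl group on the side chain. The prodrug groups differ too, dipivoxil on adefovir and disoproxil on tenofovir. At the same dose by weight and the same times, no gene passed the test of a difference between the antivirals. Limma called 0 of 120 probes, 3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.983. For Cyp26a1 the adefovir minus tenofovir difference was -0.01 with a 95% interval of -0.36 to 0.35, but both treated levels were mostly below background, so this does not show equal levels. Cyp1a2, which passed against saline after adefovir only, differed by -0.37 (-0.76 to 0.01), and Acss2, which passed after tenofovir only, by 0.35 (-0.14 to 0.85), so neither gene was shown to respond differently. The widest of the named differences was Cyp8b1 at 0.50 (-0.09 to 1.08). Nr5a2, a receptor that regulates bile acid genes, differed by -0.25 (-0.43 to -0.06), Abcb11 by -0.30 (-0.57 to -0.02) and Ebp by -0.20 (-0.41 to 0.01), each at an adjusted p of 0.983. Other differences were 0.35 for Cyp51 (-0.09 to 0.80), 0.24 for Mvd (-0.05 to 0.53), 0.25 for Cyp17a1 (-0.21 to 0.71), 0.11 for Cyp2e1 (-0.18 to 0.40), -0.11 for Cyp2a4 (-0.48 to 0.26) and -0.04 for Cyp2b10 (-0.29 to 0.22). The intervals lay within 1 log2 unit of 0 for 118 probes and within 0.5 for 103. These counts include probes below background, whose narrow intervals do not show equal levels. None of the 9 gene lists passed the test of a difference, the smallest adjusted p by fry being 0.620. The cholesterol synthesis list had a median difference of 0.14, with 17 of 18 members above 0, genes not being independent. In simulated data of this design, 42.4% of genes with a true log2 difference of 0.5 and 97.0% of those with 1 were recovered.

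The log2 ratios of the antivirals were correlated across genes, which are not independent replicates. Over 120 probes they had a Pearson r of 0.738 and a Spearman rho of 0.629, and 75.8% had the same sign. Both sets of ratios share 1 saline pool, and unchanged groups simulated against a shared pool of 10 animals gave a mean r of 0.332 (95% of simulations within 0.0858 to 0.546) and 60.8% of equal signs. The covariance was 0.0230 against a simulated 0.00484 (95% within 0.00112 to 0.00929). The treatment protocol names 5 saline animals rather than 10. A simulated pool of 5, chosen after seeing the data, gave r of 0.496 (95% within 0.278 to 0.678) and a covariance of 0.00961 (0.00460 to 0.0161). Its rho was 0.461 (0.293 to 0.615) and its share of equal signs 66.7% (58.3% to 75%), with upper ends close to the observed values. With an animal left out the observed r ran from 0.569 to 0.854, and the simulation was not repeated for these sets. The lower end lies within the range simulated for a pool of 5. The pool cannot be divided, so part of the excess may come from it. Cyp26a1, mostly below background in the treated channel, had the largest change in both groups (-1.07 in each). It adds more to the r and the covariance than any other probe, and neither was recalculated without it.

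After phenobarbital plus β-naphthoflavone, RNA levels of Cyp1a2, Cyp2b10 and Cyp1a1 rose and that of Cyp2e1 fell. Cyp1a2 rose 4.96-fold (log2 2.31, SE 0.142, SD 0.379, n = 4, adjusted p = 7.22e-09). Cyp2b10 rose at least 2.32-fold (adjusted p = 6.66e-09), a lower bound because its saline signal was below background on all 4 single-animal arrays, and was 4.10-fold higher on the pool arrays, where both channels were measured. Cyp1a1, a classic aryl hydrocarbon receptor target, rose as well (adjusted p = 1.37e-06), with at least 2.33-fold more RNA on the pool arrays. Cyp2e1 fell by 1.45 (SE 0.107, SD 0.295, n = 4, adjusted p = 5.73e-08), or 2.73-fold, in 4 of 4 animals, but median centring reduced this to -0.28 and ended the call (adjusted p = 0.266).

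In total 50 of 120 probes changed, 26 upward and 24 downward, and 44 of them had the same sign in all 4 animals. The SEs and p-values of this group use a spread shared with the antiviral animals, each the mean of 2 arrays against 1 here. With the positive-control animals fitted alone, 35 of these calls were kept and no other was made. Of the 9 CAR and PXR targets 5 rose, 1 fell and 3 did not pass (6 and 1 when adjusted over the list alone), and the list rose as a set (fry's adjusted p = 2.6e-05), upward under each scaling tried but not called with the positive-control animals fitted alone (adjusted p = 0.0923). Its risers included Cyp2b13 (2.07-fold, SE 0.109 on log2), Cyp3a13 (1.81-fold, with log2 ratios of 1.57 in animal 3 and 0.59 to 0.64 in the others), Cyp3a25 (1.43-fold) and the exporter Abcc3 (adjusted p = 1.53e-06, saline below background, 2.59-fold on the pool arrays). The member that fell was Alas1, by 1.02 (SE 0.179, adjusted p = 0.000345), while Cyp2a4 had 0.34 (adjusted p = 0.0563). Among 32 P450 genes 10 rose, 10 fell and 12 did not pass (11 and 10 when adjusted over the list alone), and fry's adjusted p for a shared upward direction was 0.00761, although the list median was 0.00 in the main scaling and -0.56 when centred on calibration spots. That set call was lost with centring on calibration spots, on luciferase spots or on Actb, Gapdh and Ppia, with the filters on dim probes and on the saline signal, in the series table and with the positive-control animals fitted alone (adjusted p from 5.03e-05 to 0.970 over 15 alternatives). Cyp2a12 rose by 0.58 on the log2 scale, while Cyp2f2 (2.08-fold, adjusted p = 1.53e-06), Cyp2c40 (1.60-fold) and Cyp4b1 (1.40-fold) fell. The Cyp17a1 call (adjusted p = 0.0181) had a saline signal below background on the single arrays, and was 2.02-fold lower on the pool arrays. Cyp26a1 was called lower (adjusted p = 0.0220, 3 of 4 animals) with saline below background on all 4 arrays. Fixed members that did not pass were Cyp2d22 at -0.21 and Cyp27a1, with saline below background, at -0.10. Of 18 cholesterol synthesis genes 8 rose, 3 fell and 7 did not pass (9 and 3 when adjusted over the list alone), with 13 of 18 above 0 and a shared direction that did not pass (fry's adjusted p = 0.106), and the list median of 0.23 turned to -0.20 with calibration-spot centring and -0.03 with luciferase centring. Cyp51 (1.81-fold, SE 0.165 on log2) and Fdps (log2 0.58) rose, whereas Sc5d (1.67-fold, adjusted p = 2.69e-05) and the isomerase Idi1 (1.61-fold, adjusted p = 0.00211) fell, and Mvk rose from a saline signal below background (adjusted p = 0.000654). Of 7 bile acid synthesis genes 2 rose, 3 fell and 2 did not pass, the same when adjusted over the list alone, and fry's adjusted p was 0.130. Scp2 fell by 0.80 (adjusted p = 1.53e-06), Cyp8b1 rose with saline below background (adjusted p = 0.0181), as did Cyp39a1 (3.49e-05), and the Cyp7a1 and Cyp46a1 calls were near background. Among 12 transporters 1 rose, Abcc3, and 3 fell (equal counts when adjusted over the list alone; fry's adjusted p = 0.148), with Slc10a1 falling by 0.70 (SE 0.0679, adjusted p = 1.30e-06) and Abcg8 and Slco1a1 measured only near background. In the nuclear receptor list 2 rose, 2 fell and 20 did not pass (1 and 1 when adjusted over the list alone, fry's adjusted p = 0.137). The coactivator Ppargc1a was lower at an adjusted p of 0.00457 with saline below background. The risers, Pparg and Nr5a1, kept their calls in only 4 and 5 of 13 alternatives. Cebpa, which also fell, kept its call in 13 of 15 but lost it without positive-control animal 1, 3 or 4. Nr1i3 had -0.04 and Ppara -0.20, both with saline below background. The 8 sterol regulation genes held no call (fry's adjusted p = 0.603), and of 6 steroidogenesis genes only Cyp17a1 passed (0.603). These list p-values are for a shared direction. For change either way fry's adjusted p was 2.43e-09 for cholesterol synthesis, 2.18e-05 for bile acid, 6.66e-11 for transporter and 0.000804 for nuclear receptor genes. It was 0.505 for both the sterol regulation and the steroidogenesis list. Acss2, outside these lists and named because it passed after tenofovir, fell by 0.51 (adjusted p = 0.0357). The reference gene Gapdh had -0.46 (adjusted p = 0.00191) at its brightest probe, 0.15 (adjusted p = 0.0270) and 0.14 at its others, and 0.43 at the brightest with median centring, while Actb had 0.22 (adjusted p = 0.0527).

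The balance of higher and lower positive-control calls depended on the scaling. Against 26 higher and 24 lower in the main scaling, centring on calibration spots gave 11 and 82, on luciferase spots 18 and 80, on Actb, Gapdh and Ppia 19 and 77, and on the array median 31 and 10, with the median of all probes moved by -0.76, -0.59, -0.52 and -0.09. Median centring also ended the Cyp2f2, Slc10a1, Sc5d, Cyp2c40 and Idi1 calls and turned Scp2 to 0.16. Fdps was lost with calibration-spot centring, with array weights and without positive-control animal 1 or 4, Cyp51 in the series table (adjusted p = 0.0905), and Mvk with centring on calibration spots, luciferase spots or Actb, Gapdh and Ppia. Cyp8b1 was lost with calibration-spot centring, array weights, no dye correction or the dye effect of the pool arrays, and without positive-control animal 1 or 3 (adjusted p up to 0.209 over 15 alternatives and 0.0792 with an animal left out). Cyp17a1 was lost with array weights or the dye effect of the pool arrays, and without animal 1 or 4 (up to 0.0796 over 14 and 0.117). Cyp7a1 and Cyp46a1 kept their calls in 6 of 13 alternatives each (adjusted p up to 0.684 and 0.853), Cyp7a1 losing its call without tenofovir animal 5 or positive-control animal 2 or 4, and Cyp46a1 without positive-control animal 1, 3 or 4. Slco1a1 was lost in fits with array weights, a random block or the positive control alone, and without animal 1 or 3, Abcg8 with the positive control alone or the dye effect of the pool arrays, and Idi1 also with array weights. Ppargc1a kept its call in 11 of 15 alternatives, Scp2 in 13 of 16 and the brightest Gapdh probe in 11 of 16. In simulated data, which gave the saline pool no deviation of its own, 25.6% of the calls fell on unchanged genes. The share was 6.80% for calls above 0.5 log2 units, of which the real data held 24. These data also gave every group the same dye effect, and equal numbers of rises and falls. Both shares therefore leave out errors of the dye correction and of the scaling, and are not the error rates of the real calls.

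On the 4 pool arrays, whose mean carries no dye effect, 47 of the 50 calls had the same sign. This held for 22 of 22 calls with the saline signal above background on at least 1 single-animal array, and for 25 of the other 28. For the 24 calls above 0.5 log2 units the count was 24. Across the 120 probes the single-animal and pool values correlated at r = 0.930, as 1 technical comparison of genes rather than of animals. The 2 arrays of an antiviral animal correlated at a median r of 0.274, or 0.613 with the dye effect removed. Those are single arrays of groups with few changes, and the 0.930 is between means of 4 arrays, so the values do not rank the quality of the arrays. Pool values were 2.41 for Cyp1a2, 1.72 for Cyp2b13, 1.15 for Cyp3a13, 1.14 for Cyp51, -1.30 for Cyp2e1, -0.93 for Cyp2f2, -1.09 for Alas1, -1.03 for Scp2 and -0.68 for Slc10a1. Sc5d was smaller there, at -0.29, and Cyp2a4 larger, at 0.94.

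**Figure D3:**
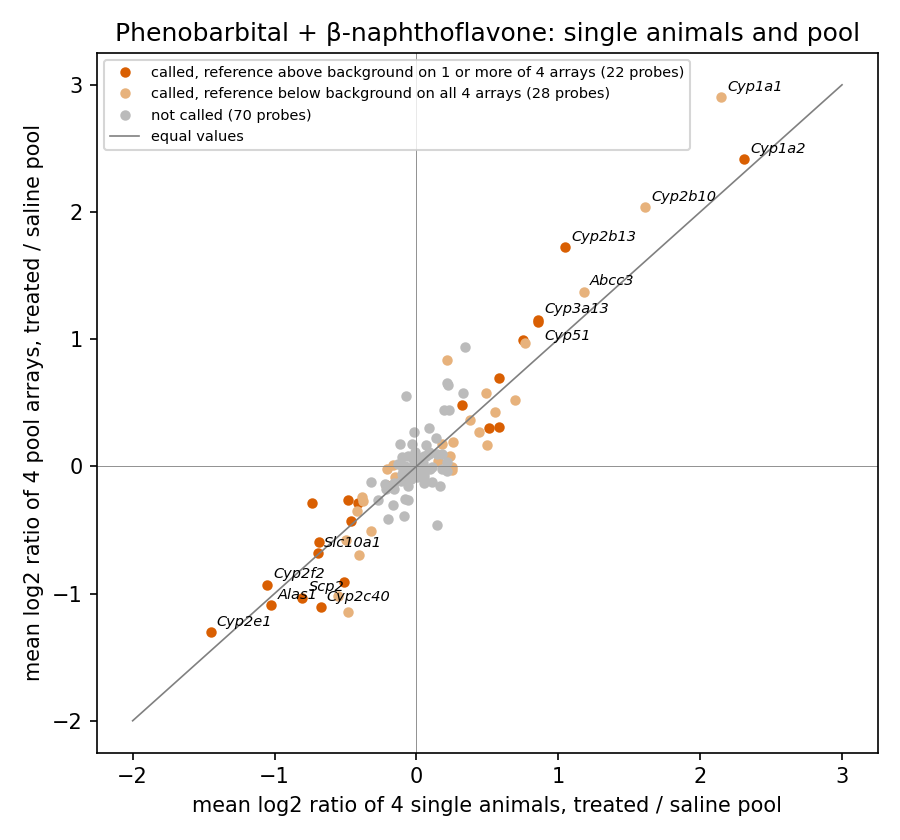
Mean log2 ratio of treated over saline RNA in the 4 single positive-control animals (horizontal axis) against the mean of the 4 pool arrays (vertical axis). Each point is a probe, coloured by whether it was called and whether the saline signal was above background, and the line marks equal values. Most points follow the line (r = 0.930), with Cyp1a2 at 2.31 and 2.41 and Cyp2e1 at -1.45 and -1.30.

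Set directly against the positive control, the antivirals had less RNA of the induced genes and more Cyp2e1. Cyp1a2 was 7.48-fold lower after adefovir and 5.77-fold lower after tenofovir (log2 -2.90 and -2.53, SE 0.191 each, adjusted p = 3.51e-08 and 1.65e-07). Cyp2e1 was 2.96-fold and 2.75-fold higher (adjusted p = 1.00e-06 and 1.98e-06), calls lost with median centring (0.154 and 0.834). Cyp2b10 and Cyp1a1 were lower in both comparisons (adjusted p = 1.23e-07 and 1.65e-07 for Cyp2b10, 3.06e-05 and 3.68e-05 for Cyp1a1), with no fold given because the positive-control saline signal was below background.

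Adefovir differed from the positive control at 39 probes, 16 higher and 23 lower, and tenofovir at 38, 16 higher and 22 lower. The CAR and PXR targets were lower as a set after adefovir (5 lower, 1 higher of 9, the same when adjusted over the list alone, fry's adjusted p = 0.00111) and after tenofovir (5 lower, 1 higher, 6 and 1 over the list alone, 0.00140), with Cyp2b13 at -1.08 in both and Cyp3a13 at -0.86 and -0.79. With calibration-spot centring both set calls were lost (adjusted p = 0.273 and 0.230). Alas1 was higher, by 1.16 and 0.97. The P450 list was lower as a set after adefovir (10 lower, 6 higher of 32, the same when adjusted over the list alone) and tenofovir (11 lower, 5 higher, 11 and 6 over the list alone; fry's adjusted p = 0.00193 and 0.00661), but its median turned to 0.65 and 0.78 with calibration-spot centring, to 0.45 and 0.50 with luciferase centring and to 0.47 and 0.37 in the series table. Both downward P450 set calls were lost there, the adefovir list being called upward in the series table (adjusted p = 0.0327), and also with centring on Actb, Gapdh and Ppia and with the filter on the saline signal (adjusted p up to 0.530 and 0.664 over 16 alternatives). The cholesterol synthesis list was lower after tenofovir (10 lower, 2 higher of 18, 12 and 3 when adjusted over the list alone, adjusted p = 0.0126, median -0.52) and did not pass after adefovir (0.0946). Its tenofovir call was lost with centring on calibration spots (median 0.35), on luciferase spots (0.07) or on Actb, Gapdh and Ppia, and with the filter on the saline signal (adjusted p from 0.00334 to 0.836 over 15 alternatives). Cyp51 differed by -0.996 and -1.35 (adjusted p = 0.00321 and 0.000276), the adefovir call being lost with calibration-spot centring and in the series table. Cyp8b1 was called lower after tenofovir (adjusted p = 0.00624, but 0.154 with calibration-spot centring) and did not pass after adefovir (0.0887). No size is given for Cyp8b1 because the positive-control saline signal was below background, and the antivirals were not shown to differ. The bile acid importer Slc10a1 was higher by 0.57 and 0.53, Scp2 by 0.72 and 0.73 and Cyp2f2 by 1.02 and 1.04. Against saline, median centring ended the positive-control calls of Slc10a1 and Cyp2f2 and turned Scp2 upward. Nuclear receptor genes were higher as a set (adjusted p = 0.0326 and 0.00959, medians 0.07 and 0.06), with 1 higher and 1 lower of 24 after adefovir, 2 higher after tenofovir and 0 when adjusted over the list alone. The adefovir call was lost in 7 of 14 alternatives, among them no background correction and adefovir with the positive control fitted alone (adjusted p from 0.00192 to 0.110), and without adefovir animal 2, 4 or 5, tenofovir animal 1 or 5, or positive-control animal 1 or 4 (up to 0.0947). The tenofovir call was kept in 14 of 14, with medians from 0.03 to 1.32. These include centrings that moved most probes upward, where an upward call says little of this list. Only 8 of its 24 genes were above background on most arrays. Cyp2d22 (0.22 and 0.34) and Cyp2a4 (-0.08 and 0.03) did not pass in either, nor did Ppara, Nr1i3, Cyp7a1 and Cyp27a1, whose positive-control saline signal was below background. Calibration-spot centring gave 81 higher and 7 lower for adefovir and 82 and 7 for tenofovir, luciferase centring 76 and 12 and 81 and 15, centring on Actb, Gapdh and Ppia 51 and 16 and 73 and 17, and median centring 7 and 27 and 13 and 35.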

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

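The tests of the positive-control signs on pool arrays, and the dye and saline-pool tests of Cyp26a1, were chosen only after the results were seen. The other tests in this part were set out beforehand, those on Cyp26a1 and cholesterol synthesis for patterns first seen in the results.

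Of 148 sets of values from 4 or 5 animals, 8 held an animal far from the others, where chance gives about 7.4. Cyp3a13 had a log2 ratio of 1.57 in positive-control animal 3 against 0.59 to 0.64 in the other animals. Apob had 0.47 in positive-control animal 2 against 0.03 to 0.04. Cyp46a1, near background, had -0.036 in positive-control animal 2 against -0.20 to -0.19. Abcb1b had 0.40 in tenofovir animal 3 against 0.01 to 0.11, and the mean of the reference genes was 0.28 in tenofovir animal 1 against 0.02 to 0.08. After adefovir, Cyp1a1, below background in both channels, had -0.22 in animal 5 against -0.12 to -0.08. The mean of the CAR and PXR targets was -0.14 in adefovir animal 1 against 0.05 to 0.12, and that of the steroidogenesis genes was 0.056 in adefovir animal 3 against -0.13 to -0.07.

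Cyp26a1 was lower in all 10 antiviral animals by a mean of -1.07 (SE 0.0834). A dye bias of the probe is argued against by the mean of -1.05 (SD 0.484) with treated RNA in Cy5 and -1.09 (SD 0.468) in Cy3, both arrays being negative in 10 of 10 animals. A loess artefact at low brightness is argued against by the 20 probes nearest in brightness, whose lowest mean was -0.22 and highest 0.23. A saline pool that happened to be high in Cyp26a1 could lower every group alike and stays open: the adefovir minus positive control value of -0.67 rests on an adefovir signal above background on 1 of 10 arrays and a positive-control saline signal below it on all 4, and decides nothing. An effect of the antivirals on this retinoic acid hydroxylase therefore remains a hypothesis, and the level in single saline animals was not analysed here.

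The positive-control calls came from arrays whose saline channel was poor. If that channel had made them, signs on pool arrays with saline RNA in Cy3 would be at chance. They matched for 22 of 22 calls with saline above background (one-sided exact binomial p = 2.38e-07) and for 12 of 13 with saline above background on a pool array only (p = 0.00171), genes not being independent. For the calls with saline below background throughout, 13 of 15 matched (p = 0.00369), but values that near the floor decide nothing, so the poor channel stays open as their cause. The treatment is open as the cause of the rest, as are the scaling choices described for this group.

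Cholesterol synthesis genes differed among adefovir animals, with list means of 0.17, -0.32, 0.24, -0.17 and -0.24, while tenofovir animals had -0.25, -0.29, -0.27, -0.15 and -0.08. Noise of single arrays is argued against by the list means of the 2 arrays of an animal, which correlated at r = 0.894 over 10 antiviral animals (permutation p = 0.00247, adjusted p = 0.00247 over 3 relations, rho = 0.721, p = 0.0235), although r fell to 0.458 without the 2 animals farthest from the median, on which it partly rests. Loess is argued against by 5 of 5 adefovir animals keeping their sign relative to the array median under median centring. A candidate explanation is shared variation of sterol-responsive genes: Acss2, outside the list, followed its mean at r = 0.899 (permutation p = 0.00025, adjusted p = 0.00075, rho = 0.842, p = 0.00366, r = 0.740 without the 2 farthest), and at r = 0.831 when each was taken from a different array (p = 0.00227, adjusted p = 0.00247, rho = 0.782, p = 0.0103, 0.558 without the 2 farthest). Feeding state and drug exposure of single animals were not tested.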

How the results depend on the processing

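Centring on Actb, Gapdh and Ppia, the filter on the positive control's saline signal and the simulated pool of 5 animals were chosen only after the results were seen. Low saline signal, a single dye orientation and the choice of scaling all limit the positive control. Genes named outside the rule for named genes, such as Cyp26a1, Acss2, Cyp3a25, Cyp4b1, Ppia, Cyp2j6 and Cyp4f14 in the positive control, are not among the values below. Of 5252 values of named genes under the alternatives, 4956 were counted as unchanged. A further 101 fell short of the threshold, 162 newly passed, 24 changed sign and 9 pool values moved beyond the spread. Of 1491 list values, 1340 were counted as unchanged, 38 fell short, 91 newly passed and 22 changed sign. A change of sign was counted only where the main or the alternative value passed. Values that passed in neither and turned are therefore among the unchanged ones, and are left out of the turned values below. Cyp26a1 passed in 14 of 14 alternatives and without each of 14 animals after either antiviral, with adjusted p from 2.77e-06 to 0.00387 for adefovir and 1.66e-06 to 0.0112 for tenofovir. Adefovir minus tenofovir gave 0 genes by limma in each alternative and with each animal left out. The correlation between the antivirals, 0.738, ranged from 0.573 with the centrings to 0.809 with array weights. Causes were not tested.

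Counts of changed genes are given against 2 for adefovir, 2 for tenofovir, 50 for the positive control (PC), 39 for adefovir minus PC, 38 for tenofovir minus PC and 10 list calls, and values of lists are medians. Median centring gave 1 for adefovir, 5 for tenofovir, 18 list calls and a technical agreement of r = 0.789 in place of 0.930, the same r as the other centrings below. In the PC it turned Apoa1 (0.94), Pparg (-0.040), Ppargc1a (0.063), Scp2 (0.16), Gapdh (0.43) and the bile acid list (0.16), and in tenofovir minus PC Cyp2a4 (-0.91), the bile acid list (-0.40) and the reference genes (-0.28). Calibration-spot centring gave 1, 1, 93, 88 and 89 genes and 16 list calls. In the PC it turned Cyp21a1 (-0.56), Mvk (-0.032), Pparg (-0.71), Nr5a1 (-0.64), Star (-0.80) and the P450 list (-0.56). It also turned the steroidogenesis list (0.99 for adefovir minus PC, 1.20 for tenofovir minus PC), the P450 list (0.65 and 0.78) and cholesterol synthesis in tenofovir minus PC (0.35). Luciferase centring gave 1, 32 (27 higher), 98, 88 and 96 genes and 24 list calls. In the PC it turned Apoa1 (0.45), Cyp21a1 (-0.38), Pparg (-0.54), Nr5a1 (-0.46) and Star (-0.63). In adefovir minus PC it turned the bile acid (0.46), steroidogenesis (0.78), reference (0.39) and P450 (0.45) lists, and in tenofovir minus PC cholesterol synthesis (0.070), steroidogenesis (0.91) and P450 (0.50). Centring on Actb, Gapdh and Ppia gave 96 genes for the PC, 67 for adefovir minus PC and 90 for tenofovir minus PC, and turned Apoa1 (0.52), Pparg (-0.47), Nr5a1 (-0.39), Star (-0.56) and Gapdh (0.0051) in the PC and steroidogenesis in tenofovir minus PC (0.72). These centrings moved the median of all probes by 0.16, 0.13 and -0.07 for adefovir and 0.40, 0.29 and 0.17 for tenofovir, in the order calibration, luciferase, Actb with Gapdh and Ppia.

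Without background correction there were 17 list calls, and Cyp46a1 (0.074) and the bile acid list (0.074, and -0.052 for tenofovir minus PC) turned. The dim-probe filter gave 5 genes for tenofovir over 67 probes. Array weights gave 5 (2 higher), 9 (3 higher) and 30, the fit of all arrays with the animal as a random block 12 for tenofovir (2 higher) and 40 for the PC, and the compared group alone 1 for adefovir, 9 for tenofovir and 35 for the PC. Arrays with treated RNA in Cy3 alone gave 29 for tenofovir (17 higher) and turned Soat1 (-0.29); those in Cy5 gave 17 for adefovir (10 higher) and 16 for tenofovir (11 higher). The series table, with 39 probes, gave 0, 1, 19, 10 and 15 genes, and the P450 list at -0.34 for the PC, 0.47 for adefovir minus PC and 0.37 for tenofovir minus PC. The filter on the PC's saline signal, with 18 probes, gave 11, 10 and 10. Nr5a1 was -0.0041 on the pool arrays.

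With 1 animal left out, counts ranged over 1 to 3 for adefovir, 1 to 4 for tenofovir, 37 to 57 for the PC, 34 to 45 for adefovir minus PC, 34 to 44 for tenofovir minus PC, 0 to 0 for adefovir minus tenofovir and 8 to 16 for list calls, the correlation between antivirals over 0.569 to 0.854 and the technical agreement over 0.906 to 0.940. The count was 1 without adefovir animal 2, 3 or 4 (Cyp1a2 lost) and without tenofovir animal 1, 2 or 4 (Acss2 lost, as also without animal 3), 4 for tenofovir without adefovir animal 3, and list calls reached 16 without PC animal 2.

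Replicate numbers were not taken to pair the animals, since not every pair of equal number correlated above 0.1. Deviations from group means correlated at 0.06, 0.27, -0.12, 0.13 and -0.21 for adefovir with tenofovir, 0.37, 0.07, -0.44 and -0.0077 for adefovir with PC and 0.19, 0.29, 0.18 and -0.16 for tenofovir with PC. The own number was the best partner for 2 of 5, 1 of 4 and 3 of 4 animals. With the replicate block there were 0 genes for adefovir minus tenofovir, 36 for adefovir minus PC and 42 for tenofovir minus PC. Not run were keeping spots with a scanner mark (the files hold no such column), centring on the full list of reference genes (2 of them measured) and a block for slide or scan date (no date, 1 animal per slide).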

Other observations

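All tests reported in this part were set out beforehand.

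Nuclear receptors and their partners were mostly too dim for these arrays, 8 of the 24 being above background. Nr2f6, an orphan receptor, had 0.12 and 0.11, and Nr1d2, a clock-linked repressor of heme and lipid genes, had 0.25 after tenofovir (adjusted p = 0.203). The reference gene Ppia had 0.17 after tenofovir (adjusted p = 0.231) and rose by 0.32 in the positive control (adjusted p = 0.00619). P450 genes outside the fixed set also fell in the positive control with saline below background on the single-animal arrays, among them Cyp2j6 (adjusted p = 0.00136) and Cyp4f14 (adjusted p = 0.00329), at -0.35 and -0.58 on the pool arrays. These genes were chosen after their values were seen.

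The animals were divided anew into groups of the real sizes, 100 of 126 divisions being drawn for each comparison. For adefovir against tenofovir, limma called 0 genes in the real division and at most 0 in the others. A count of 0 is reached by any division, here 100 of 100, so this says nothing about chance. For adefovir against the positive control the real division gave 39 genes, more than any other; 1 of 100, the real one, reached that number, and the highest other gave 36. For tenofovir against the positive control the real division gave 38, again 1 of 100, and the highest other gave 17. Both of those highest divisions set the 4 positive-control animals and 1 antiviral animal against 4 antiviral animals, and so nearly mirror the real one. For both, a division by chance is argued against by these counts. They cannot tell the treatment from the array design of the positive control. That group had 1 array per animal, 1 dye orientation and a poor saline channel.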
